A study of Caenorhabditis elegans with 2 samples.

How the data were processed

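The data are chromatin immunoprecipitation followed by sequencing (ChIP-seq), which enriches the DNA that a protein is bound to and finds the enriched places by their reads. The protein was F13H6.1, the product of bcl-11, a C. elegans gene named after the mammalian BCL11 zinc finger proteins. It carried a GFP-FLAG tag at its C terminus in the transgenic strain OP471, which also carries a mutant allele of unc-119. The unc-119 gene is commonly used as a marker for transformation. Whole late embryos were collected 5 hours after they had been synchronized by bleaching, and the tagged protein was pulled down with an antibody against GFP. The series has 1 group with 2 biological replicates, so it holds no comparison between conditions. The comparisons set regions that passed the authors' reproducibility threshold against regions that did not, and the replicates against each other.

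Per the labels and the lists of files that go with them, the authors aligned the reads to the worm genome, called enriched regions in each replicate and in the pooled reads against a control library, and listed them at a permissive level. They then kept the pooled regions that passed a threshold on the irreproducible discovery rate (IDR), a measure of how well the ranks of a region hold between replicates. The aligner, the peak caller, their versions and the IDR level are not given in the sources used here. Each deposited region has a start, an end, a summit and a signal that the authors' peak caller gave it. The scale of this signal is not stated, so it served only to rank or filter regions within a list. Sequencing depth per library is unknown from the lists, and the control libraries and the signal tracks were not analysed here. All lists exist on ce11 (WBcel235) and on ce10. The ce11 lists gave every coordinate and every main value, and the ce10 lists were used alone, without converting positions.

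In the thresholded ce11 list all 1065 regions were also in the pooled list, and they were its 1065 regions of highest signal. These are called sites here. The background was the 20419 pooled regions that overlapped no site. Another 340 pooled regions overlapped a site without being one and were left out. The list holds 3 repeated intervals that differ in their summits, and these were kept. Positions are 1-based.

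Genes came from the Ensembl release 115 annotation of WBcel235, with mitochondrial gene names from RefSeq. The promoter window ran from 1000 bp upstream to 500 bp downstream of any annotated transcript start, and a gene was counted as bound when a summit lay in its window. A summit was placed in 1 class in this order: mitochondrial genome, within 100 bp of a nuclear tRNA, snoRNA or snRNA gene, coding exon, UTR, intron, other noncoding gene, intergenic. Coding exon, UTR and intron refer to any protein-coding gene, which need not be the gene named with the site. Shares are given with 95% Wilson intervals and were compared with two-sided Fisher's exact tests at a threshold of 0.05, with Benjamini-Hochberg adjustment within each family of tests. The families were the chromosomes, the gene lists, the 6-letter words and the summit classes. Odds ratios have 95% intervals on the log scale, with 0.5 added to each cell where a count was 0. The 42 gene lists held tissue markers, signalling pathways, complexes and gene families. Each was tested against the other genes of its class, protein-coding or noncoding. Of their members, 8 could not be matched to the annotation and 5 were matched by an older name.

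DNA words were sought on both strands in windows of 50 bp on each side of a summit, with a second window 300 bp to the left as a local comparison by exact McNemar test. TGACCA was tested by name because mammalian BCL11A binds it, and all 2080 6-letter words were tested with their reverse complements merged. Base composition was handled by Mantel-Haenszel odds ratios over 10 strata of GC count, and by a background of 2 sub-threshold regions per site matched on GC count and promoter window. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and the plots matplotlib 3.10.9.

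The code was tested on simulated data. Over 100 rounds of random bound genes, 3 of 4200 list tests without an effect were called, and 500 of 500 planted lists were found. Bound genes were drawn independently and planted lists were of middle size. Neighbours that share a site and the smallest lists were therefore not tried. For words, 20 rounds gave 0 calls without an effect and 20 of 20 planted words. Windows without an effect were drawn at random from the sub-threshold windows, so both sides had the same expected GC content. The 0 calls therefore say nothing about words that differ through the GC content of real sites. For shares, 9 of 200 rounds without an effect were called, and 200 of 200 rounds with an odds ratio of 2 were found, with a median estimate of 2.02.

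The genes and sites named in the text were chosen by rule. They are bcl-11 and unc-119, the 20 sites of highest signal farther than 50 kb from both, the 4 bound genes of highest signal in each list past the threshold and up to 2 in every other list, and the 5 words of highest odds ratio among those past the threshold and present in at least 5% of site windows. Comparisons, lists, this rule and the alternatives were fixed before the data were examined, except where the text says that a choice came later. The alternatives were a stricter threshold, each replicate alone, other promoter and word windows, other backgrounds, other overlap rules, nearest starts and the ce10 lists. With nearest starts, each site went to the nearest protein-coding and the nearest noncoding transcript start, at any distance. Sites and genes are not replicates, so the p-values describe these lists and not the spread between animals, and intervals cover counting error only.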

Results

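ChIP-seq of GFP-FLAG-tagged F13H6.1, the product of bcl-11, was recorded in whole late embryos of C. elegans in 2 biological replicates of 1 group. On the ce11 build (WBcel235), replicate 1 had 19517 permissively called regions, replicate 2 had 21972, and the pooled reads had 21824. The reproducibility threshold kept 1065 sites, 4.88% of the pooled regions, with a median width of 456 bp (range 114 to 1049 bp) and a covered length of 439.9 kb. On ce10, taken alone, 1362 sites were kept. Depth per library is unknown from these lists.

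The first question was how far the replicates gave the same places. The same few loci led both lists, among them the region upstream of K12H4.5 and a region of the mitochondrial genome, which ranked first and second in each. Of the 1065 highest regions of replicate 1, 762 (71.5%, 95% Wilson interval 68.8 to 74.2) overlapped 1 of the 1065 highest of replicate 2, against 3.10% (2.85 to 3.35) of its lower regions, an odds ratio of 78.8 (67.3 to 92.1). From replicate 2 the share was 69.5% (66.6 to 72.2). The threshold itself used both replicates, so values over the sites alone restate that selection in part. All 1065 sites overlapped a region of replicate 1 and 1064 a region of replicate 2. Summits lay within 100 bp of a replicate summit for 1031 sites in replicate 1 and 1047 in replicate 2. By rank, 741 sites (69.6%) lay among the 1065 highest of both replicates and 19 among those of neither. Across the 10576 pooled regions found in both replicates (48.5%), Spearman's rho of the replicate signals was 0.547, and across 1064 sites it was 0.586. These correlations are across regions within 1 experiment, and regions are not independent replicates.

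The strongest sites lay upstream of single protein-coding genes such as K12H4.5 and eel-1, between divergent neighbours such as ears-2 and uncp-18, at small nucleolar RNA genes and in the mitochondrial genome. The strongest of all lay between genes on chromosome III from 8043737 to 8044209, 532 bp from a transcript start of K12H4.5, with a signal of 1223. Among the 20 named sites, idhg-1, which encodes a subunit of mitochondrial isocitrate dehydrogenase, and mlcd-1, which encodes malonyl-CoA decarboxylase, shared an intergenic site (III, 4568591 to 4568878, signal 416). The genes ears-2, for the mitochondrial glutamyl-tRNA synthetase, and uncp-18 shared another (IV, 390337 to 390641, signal 394.8). So did tasp-1, a threonine aspartase gene, and K01G5.10 (III, 10759082 to 10759398, signal 396). Intergenic sites also lay upstream of eel-1, a HECT-type ubiquitin ligase gene (IV, 3050432 to 3050887, signal 407.8), and near the noncoding F52D10.7 and ftt-2, which encodes a 14-3-3 protein (X, 11605727 to 11606241, signal 378). An intronic site lay 927 bp from a transcript start of lit-1, the gene of the Nemo-like kinase of Wnt signalling (III, 13712955 to 13713320, signal 390.8). Intronic sites also stood in the window of M01F1.9 (III, 3499839 to 3500252, signal 832.5) and 3371 bp from the nearest start, that of Y111B2A.12 (III, 12612495 to 12612860, signal 469.6). The site ranked 11 (II, 1246852 to 1247270, signal 432) was in the window of the noncoding F47F6.13, inside an intron of lin-42. The gene lin-42, the worm Period homologue that times larval development, held 5 sites between its ends at 1233236 and 1252359, a count chosen after its values were seen. Sites at noncoding genes included F13D11.9 on X (5811894 to 5812465, signal 675.6) and an intergenic one 1286 bp from the piRNA gene 21ur-13313 (III, 4282026 to 4282553, signal 396.2). In the mitochondrial genome the named sites lay in the promoter windows of the tRNA-Ala gene, 810 bp from its start (12208 to 12591, signal 896.3), of the tRNA-Cys gene, at 326 bp, and COX2 (9007 to 9353, signal 769.7), of the tRNA-Thr gene, at 312 bp, with ND4 and COX3 (5910 to 6365, signal 446.7), and of COX1, at 375 bp (7974 to 8429, signal 404.9). This genome is 13794 bp long with closely spaced starts, so windows of this width cover much of it. Lying in such a window therefore says little there.

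The sites gathered near transcript starts and avoided coding sequence. K12H4.5, idhg-1, ears-2 and tasp-1 are examples of sites between genes and close to a start. Of the 1065 sites, 861 (80.8%, 78.4 to 83.1) had their summit in a promoter window, against 51.2% (50.5 to 51.9) of sub-threshold regions, an odds ratio of 4.02 (3.44 to 4.69, exact p = 8.66e-86). The same windows cover 45% of the genome. Against only the 1065 sub-threshold regions of highest signal the odds ratio fell to 1.95 (1.60 to 2.39). With protein-coding starts alone, chosen after seeing the data, the shares were 58.5% and 37.8%, with windows covering 31.9% of the genome (odds ratio 2.32, exact p = 2.18e-40). The summit classes were also drawn up after seeing the data. Intergenic summits made up 53.5% of sites and 34.7% of the background (odds ratio 2.17). Introns held 18.8% against 31.4% (0.506), UTRs 2.44% against 6.32% (0.371), and coding exons 16 sites, 1.5%, against 23.1% (0.0508). Other noncoding genes held 7.23% against 3.08% (2.45). The adjusted p of these classes was at most 1.30e-08 in Fisher's exact tests.

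**Figure D1:**
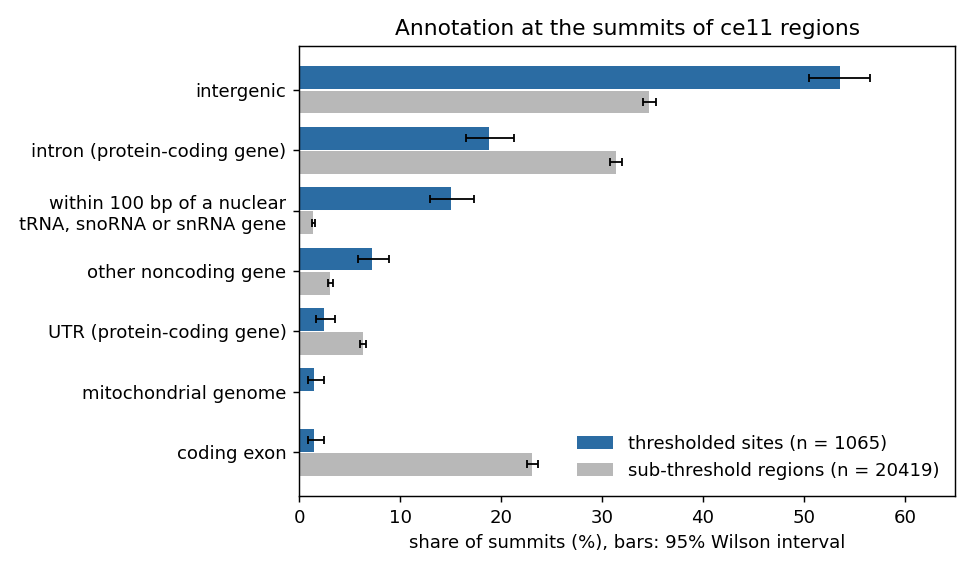
Share of summits in each annotation class, in percent, for the 1065 sites (blue) and the 20419 sub-threshold regions (grey) on ce11, with 95% Wilson intervals. Sites exceed the background in intergenic DNA (53.5% against 34.7%) and near nuclear tRNA, snoRNA and snRNA genes (15% against 1.42%), and lie below it in coding exons (1.5% against 23.1%).

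Genes for small structural RNAs carried far more sites than other places. Nuclear tRNA genes, which RNA polymerase III transcribes, and snoRNA genes, whose products guide the modification of ribosomal RNA, stood out. Summits within 100 bp of a nuclear tRNA gene made up 10.0% of sites (107, 8.38 to 12) and 0.994% of the background, an odds ratio of 11.1 (8.72 to 14.2, exact p = 3.34e-61), and reached 113 of 612 genes. The median distance of these summits from the gene's centre was 32.5 bp. For snoRNA genes the shares were 4.32% (46 sites) and 0.304%, an odds ratio of 14.8 (10.1 to 21.8, exact p = 1.49e-31), with 47 of 346 genes reached. For snRNA genes 7 sites gave an odds ratio of 5.40 (exact p = 0.000816). Within 100 bp of microRNA genes lay 3 sites, which gave 2.22 (0.670 to 7.33, exact p = 0.172). The 100 bp distance was chosen after seeing the data. The snoRNA genes W03C9.9 (II, 11960652 to 11960998, signal 475.7), ZK994.7 (V, 8500401 to 8500714, signal 444.4), C51F7.3 and C51F7.4 (V, 12303479 to 12303815, signal 434.3) and T03F7.8 (V, 11314046 to 11314373, signal 412.6) were among the 20 named sites. The nuclear tRNA genes with the strongest summits within 100 bp, named after their values were seen, were C04A11.t1 (X, 13665422 to 13665729, signal 359.6), C37A2.t1 (I, 6781587 to 6782042, signal 286.5) and C42D8.t1 (X, 5085404 to 5085859, signal 271.7). The share near snoRNA genes was 16% among the 100 strongest regions and 0.224% from rank 8001 on. The share near tRNA genes was 11 to 13.2% within the first 500 and 0.449% from rank 8001 on.

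**Figure D2:**
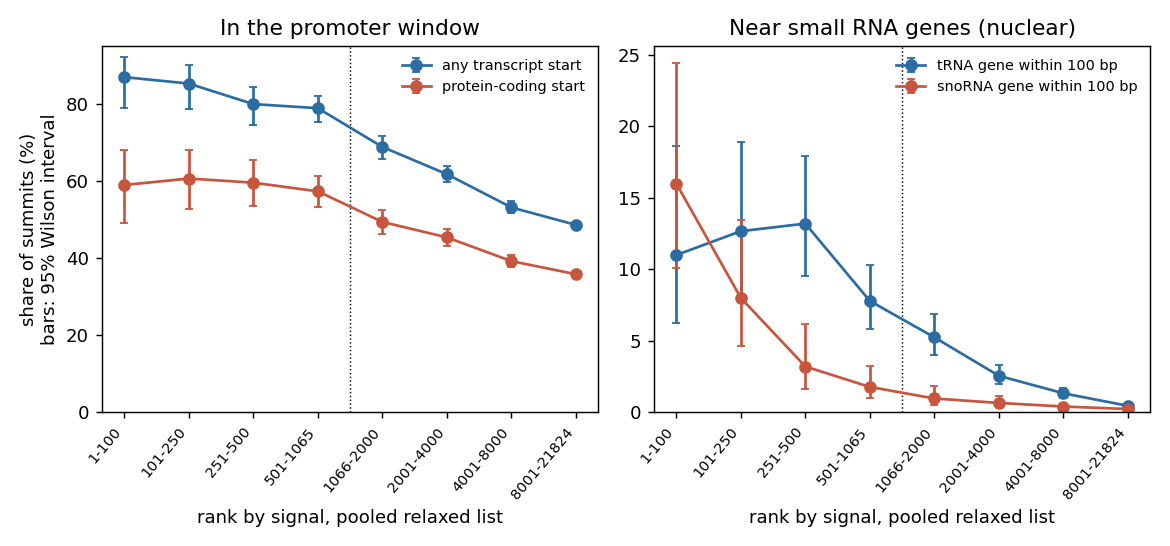
Share of summits, in percent, in promoter windows (left) and within 100 bp of nuclear tRNA or snoRNA genes (right), by rank of signal in the pooled list, with 95% Wilson intervals and a dotted line at the reproducibility threshold. The share with any transcript start falls from 87% among ranks 1 to 100 to 48.6% from rank 8001 on, and the snoRNA share from 16% to 0.224%.

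Which groups of genes had sites was asked with the 42 fixed lists. Control libraries were not analysed here, so whether sites at any of the lists mark binding of the protein was not tested. Genes of ribosomal proteins, chaperones, body wall muscle, developmental timing and chromatin complexes were counted as bound more often than other protein-coding genes. The tRNA, snoRNA with snRNA, and microRNA genes were bound more often than other noncoding genes. Most of those noncoding genes were piRNA genes, with 49 of 15363 bound (0.319%). Of 7764 genes typed as ncRNA 452 were bound (5.82%), so the noncoding odds ratios depend on this background. In all, 1555 genes had a summit in their promoter window, 788 of them among 19985 protein-coding genes (3.94%), and 13 lists passed the adjusted threshold, 8 of them higher. Of 82 ribosomal protein genes 20 were bound (24.4%, odds ratio 8.04, 4.83 to 13.4, adjusted exact p = 4.22e-10), led by intergenic sites at rpl-3 (III, 3867442 to 3867715, signal 346.6), rps-24 (IV, 385456 to 385706, signal 281.4), rpl-15 (IV, 654815 to 655063, signal 218.6) and rpl-35 (III, 7854594 to 7854788, signal 205.2). With replicate 1 alone 14 of the 82 were bound, an odds ratio of 5.24 (adjusted exact p = 2.16e-05). For 5 of the 20, rpl-7A, rpl-15, rps-12, rps-23 and rps-26, the same site also counted for a snoRNA gene, and 12 of the 20 had a site among the 1065 highest of both replicates. Of 60 heat shock and chaperone genes 12 were bound (odds ratio 6.17, 3.26 to 11.7, adjusted exact p = 2.67e-05). The strongest were the DnaJ-type co-chaperone genes dnj-29 (I, 14113168 to 14113373, signal 231.2) and dnj-28 (I, 2996276 to 2996484, signal 208.0), the cytosolic chaperone gene hsp-90, with an intronic site (V, 14685712 to 14685825, signal 196.7), and the mitochondrial chaperonin gene hsp-60 (III, 1618889 to 1619344, signal 161.8). Of the 12, 8 had a site among the 1065 highest of both replicates. With each site given instead to its nearest protein-coding and nearest noncoding start, at any distance, this list no longer passed (odds ratio 1.82, adjusted exact p = 0.383). Of 634 tRNA genes 149 were bound, 20 of them mitochondrial (odds ratio 12.8, adjusted exact p = 3.94e-92). The 4 of highest signal were the mitochondrial genes for tRNA-Ala, tRNA-Cys, tRNA-Met and tRNA-Asp, the last 3 at 1 site that also counts for tRNA-Gly with the same signal. Of 475 snRNA and snoRNA genes 76 were bound (odds ratio 7.11, adjusted exact p = 1.39e-33).

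Smaller groups passed with fewer genes. Of 43 body wall muscle genes 8 were bound (odds ratio 5.62, adjusted exact p = 0.00144). They included unc-112, the kindlin of muscle attachments (V, 14696868 to 14697323, signal 157), the cofilin gene unc-60 (V, 1474495 to 1474950, signal 141.6), the paramyosin gene unc-15 (I, 7383120 to 7383575, signal 93.61) and the myosin heavy chain gene unc-54 (I, 14863343 to 14863798, signal 92.09), all at intergenic sites. Only the sites of unc-112 and unc-60 were among the 1065 highest of both replicates. The other 6 were not, with act-4, dim-1 and mup-2 ranked 1599, 2845 and 3217 in replicate 1, and unc-15, unc-54 and clik-1 ranked 1134, 1397 and 1106 in replicate 2. Of 11 heterochronic genes, which time larval cell fates, 4 were bound (odds ratio 14, adjusted exact p = 0.00333), and with replicate 1 alone 5 (21, adjusted exact p = 0.000218). These were the RNA-binding protein gene lin-28, in a UTR (I, 8409672 to 8410127, signal 158.6), lin-66, in intergenic DNA (IV, 13887501 to 13887623, signal 158.6), the microRNA Argonaute gene alg-1, in a UTR (X, 13950720 to 13951175, signal 134.6), and lin-42, in a coding exon (II, 1239584 to 1240039, signal 120.3). Of 27 SWI/SNF, NuRD and Polycomb-like genes 5 were bound (odds ratio 5.57, adjusted exact p = 0.0141). The strongest were swsn-3 (III, 2768758 to 2768920, signal 206.3) and pbrm-1 (I, 7500513 to 7500649, signal 198.8), both in introns, swsn-7 at a noncoding gene (II, 8028259 to 8028714, signal 172.7) and the NuRD gene lin-40 in intergenic DNA (V, 3704008 to 3704172, signal 164.9). Of 261 microRNA genes 20 were bound (odds ratio 2.88, adjusted exact p = 0.000457), among them cel-mir-52 (IV, 14033082 to 14034130, signal 298.9) and cel-mir-51 (IV, 11026111 to 11026303, signal 169.5) at noncoding genes, and cel-mir-54 with cel-mir-55 in an intron (X, 13145189 to 13145644, signal 155.8). That site also counted for cel-mir-56, and cel-mir-64, cel-mir-65, cel-mir-66 and cel-mir-229 shared another (III, 2171938 to 2172393). Genes at a shared site are not independent in this test. The bound share of microRNA genes, 7.66%, lay near the 5.82% of genes typed as ncRNA, while most of the background was piRNA genes. When genes with at least 1 permissively called region served as the background, none of these smaller groups passed. Odds ratios were then 2.37 for muscle, 5.53 for heterochronic genes, 2.96 for the chromatin complexes and 1.56 for microRNA genes, with adjusted exact p of 0.177, 0.0904, 0.177 and 0.239. Muscle and microRNA genes also lost the call among the 532 strongest sites (odds ratios 2.37 and 1.49, adjusted exact p = 0.568 and 0.680), and the chromatin complexes with windows of 500 bp upstream (odds ratio 1.21, adjusted exact p = 0.856).

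**Figure D3:**
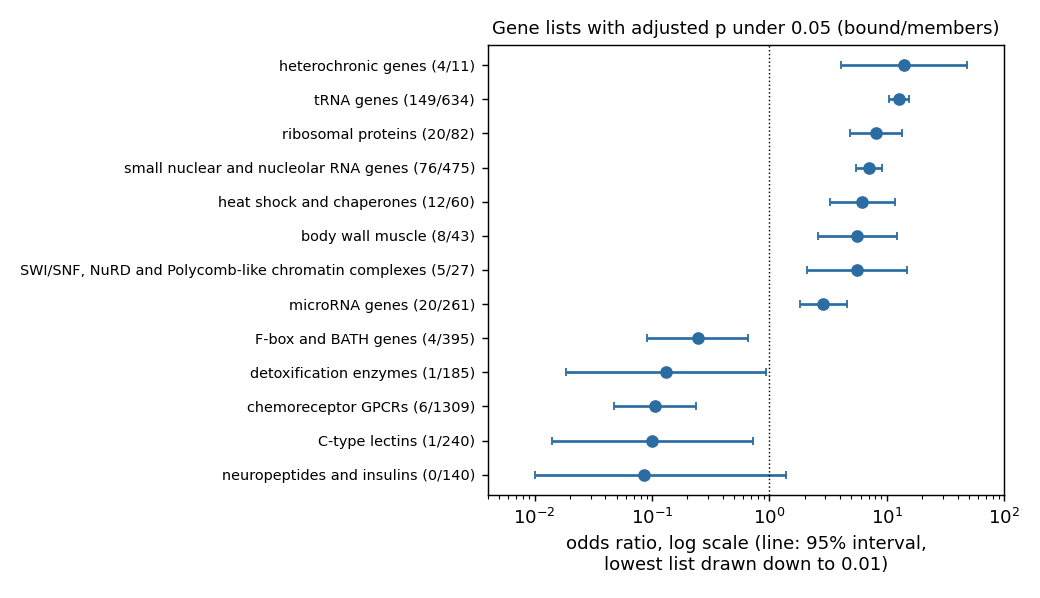
Odds ratio (log axis) of having a site in the promoter window for the 13 lists with adjusted p under 0.05, against the other genes of the same class, with 95% intervals and the bound and total members in brackets. The 8 higher lists range from 2.88 (microRNA genes) to 14 (heterochronic genes), and the 5 lower lists lie at 0.245 or below.

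Large families that act in sensory cells, defence and neuropeptide signalling were bound less often. Of 1309 chemoreceptor genes 6 were bound (0.458%, odds ratio 0.105, 0.0471 to 0.236, adjusted exact p = 2.92e-15), led by sre-23 (I, 8259431 to 8259714, signal 339.1), sre-1 (II, 7708719 to 7708832, signal 201.6), sri-5 (I, 11182265 to 11182720, signal 117.6) and srh-2 (V, 731295 to 731750, signal 111.3). Of 395 F-box and BATH genes 4 were bound (odds ratio 0.245, adjusted exact p = 0.00430), namely fbxb-85, math-33, fbxc-44 and bath-42, all at intergenic sites. Of 240 C-type lectin genes only clec-126 was bound (adjusted exact p = 0.00516), of 185 detoxification genes only gst-27 (adjusted exact p = 0.0374), and of 140 neuropeptide and insulin genes 0 (adjusted exact p = 0.0250). For 4 of the 12 bound members of the lower lists, sre-23, srh-269, clec-126 and gst-27, the site lay within 100 bp of a nuclear tRNA, snoRNA or snRNA gene, against 0 of the 49 bound members of the higher protein-coding lists, a count made after seeing the data and not tested. The sites of sri-5, fbxc-44 and bath-42 fell below the 1065 highest regions of replicate 1, and those of srh-269 and clec-126 below those of replicate 2. Against genes with a permissively called region none of the 5 lower lists passed, with chemoreceptors at an odds ratio of 0.368 (adjusted exact p = 0.0651) and the others at adjusted exact p from 0.0915 to 0.629. With the 532 strongest sites, where fewer genes were bound, only the chemoreceptors passed among them (odds ratio 0.104). The odds ratio was then 0.242 for F-box and BATH genes, 0.0992 for C-type lectins, 0.171 for neuropeptides and insulins and 0.261 for detoxification genes. With replicate 2 alone the detoxification genes did not pass (0.274, adjusted exact p = 0.143). With windows of 500 bp upstream neither they (0.170, adjusted exact p = 0.172) nor neuropeptides and insulins did (0.111, adjusted exact p = 0.0910), and with nearest starts the latter did not either (0.436, adjusted exact p = 0.316).

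The other 29 lists did not pass. Mammalian BCL11 proteins act in neurons and blood cells, and of the neuronal lists 3 of 36 pan-neuronal genes were bound (odds ratio 2.22, adjusted exact p = 0.372), among them syd-2 and unc-76, which act in synapse assembly and axon growth. Of 43 neuronal fate transcription factor genes 0 were bound, of 95 homeobox genes 0 (adjusted exact p = 0.156) and of 85 acetylcholine receptor genes 0 (adjusted exact p = 0.205). With replicate 1 alone 2 homeobox genes were bound (odds ratio 0.538), and with replicate 2 alone 1 (0.267). Axon guidance had 4 of 38, including vab-10 and unc-115 (odds ratio 2.88, adjusted exact p = 0.161), and passed with replicate 2 alone (4.76, adjusted exact p = 0.0103) but not with replicate 1 alone (2.15, adjusted exact p = 0.373). Wnt signalling had 4 of 29, including lit-1 and mom-1 (odds ratio 3.91, adjusted exact p = 0.0781). The pan-neuronal, Wnt, TGF-beta and EGF lists passed with windows of 2000 bp upstream, at odds ratios of 3.67, 4.78, 4.31 and 5.39, and the homeobox list passed there as lower (adjusted exact p = 0.0278). The hypodermis list, with vab-10 alone of 31 genes, stood at 0.812 and passed at 3.86 with nearest starts. The long intergenic RNA list, with 5 of 194 genes including linc-82 and linc-91, stood at 0.902 and passed at 2.34 there. Single genes of other lists had strong sites, such as the maternal zinc finger gene mex-1 (II, 11967574 to 11967878, intergenic, signal 364.3), the retinoblastoma homologue lin-35 (I, 5807263 to 5807584, intergenic, signal 322.0) and nhr-48 (X, 15707607 to 15707745, intergenic, signal 217.9).

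By chromosome, X and the mitochondrial genome held more sites than the background, and the central parts of the autosomes did so too. The X chromosome held 21.5% of sites (229, 19.1 to 24.1) and 17% of sub-threshold regions, an odds ratio of 1.34 (1.15 to 1.56, adjusted exact p = 0.000729). Of the 612 nuclear tRNA genes 276 lie on X, and 57 of the 107 sites near tRNA genes were there. Without sites near tRNA, snRNA and snoRNA genes, a step chosen after seeing the data, the X share was 19% (odds ratio 1.16, adjusted exact p = 0.187). With promoter sites alone it was 20.9% (1.22, adjusted exact p = 0.0627), and against the 1065 strongest sub-threshold regions it lay below theirs, 21.5% against 22% (0.973, adjusted exact p = 0.834). The mitochondrial genome held 16 sites and 1 sub-threshold region (adjusted exact p = 1.36e-19). This genome is only 13794 bp long. Control libraries were not analysed here, so whether its sites mark binding of the protein was not tested. Chromosomes I to V did not pass, with odds ratios from 0.833 for V to 1.06 for III, although II and V were lower with replicate 2 alone (adjusted exact p = 0.0356 and 0.0227). Chromosome V was also lower on ce10 (0.823, adjusted exact p = 0.0347) and without the regions within 50 kb of bcl-11, a step chosen after seeing the data (0.763, adjusted exact p = 0.00894), and IV was lower with promoter sites alone (0.771, adjusted exact p = 0.0342). On the autosomes 504 of 820 sites (61.5%, 58.1 to 64.7) lay in the central 50% of the chromosome, against 46.1% of the background (odds ratio 1.86, 1.61 to 2.15, exact p = 9.10e-18).

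The DNA at the summits was searched for TGACCA, the word bound by mammalian BCL11A. TGACCA was not measurably more frequent at sites than in the background, while CG-rich words and others such as GAGAGA were. It stood in 40 site windows (3.76%, 2.77 to 5.07) and in 3.70% of sub-threshold windows, an odds ratio of 1.01 (0.734 to 1.40, exact p = 0.934), and ranked 78 of 180 words of the same composition. Over 10 strata of GC count the odds ratio was 0.930 (0.667 to 1.30). Windows 300 bp away held it in 2.07%, and 39 sites had it only at the summit and 21 only in the flank (exact McNemar p = 0.0273). Mean GC content was 50% at sites, 42.2% in the background and 36.7% in the flanks. The comparison with the flanks was not adjusted for this, so it cannot separate the word from base composition. Of all 6-letter words 506 were more and 483 less frequent at sites. GCGCGC had the highest odds ratio among words in at least 5% of windows, with 10.5% against 2.22% (5.18, 4.17 to 6.43, adjusted exact p = 8.05e-35). AGCGCG, ACGCGC, CGCACG and CGCGCG followed at 4.17, 4.03, 4.03 and 4.02, and GAGAGA, in 27.9% against 10.9% of windows, had the lowest p. Against the background matched for GC content and promoter window, 191 words were more and 223 less frequent. GCGCGC then stood at 2.46 (adjusted exact p = 6.51e-08) and AGCGCG at 2.68 (adjusted exact p = 7.82e-09). Words with fewer CG pairs stood above them there, named after their values were seen: TTGCAA at 2.84, ACGCTC at 2.81, GTACAC at 2.77 and AGAGAC at 2.76 (adjusted exact p = 9.86e-17).

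The tagged gene itself and unc-119, which is commonly used as a marker for transformation, were examined. Extra copies in a transgene can raise reads over their own sequence. Around bcl-11 (V, 6356025 to 6362997, plus strand) sites were dense, and the nearest surroundings of unc-119 held none. Within 50 kb of bcl-11 lay 13 sites, with summits from 6342676 to 6362566. In 933 other windows of the same length the median was 1 and the highest count 7. The strongest of the 13 was upstream of the gene in intergenic DNA (6351063 to 6351518, signal 241.0, rank 60), and 4 lay inside the gene, 3 in introns and 1 in a UTR. With replicate 1 alone 8 of its 1065 highest regions fell in this window, and with replicate 2 alone 12. Of the permissively called pooled regions 29 lay between 6337689 and 6368279, 3 of them in coding exons. No further region lay within 11.9 kb on the left and 32.3 kb on the right. At unc-119 (III, 10902641 to 10908935) 0 sites lay within 20 kb and 1 within 50 kb (signal 228.6, rank 73), although 18 permissively called pooled regions lay within 20 kb.

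**Figure D4:**
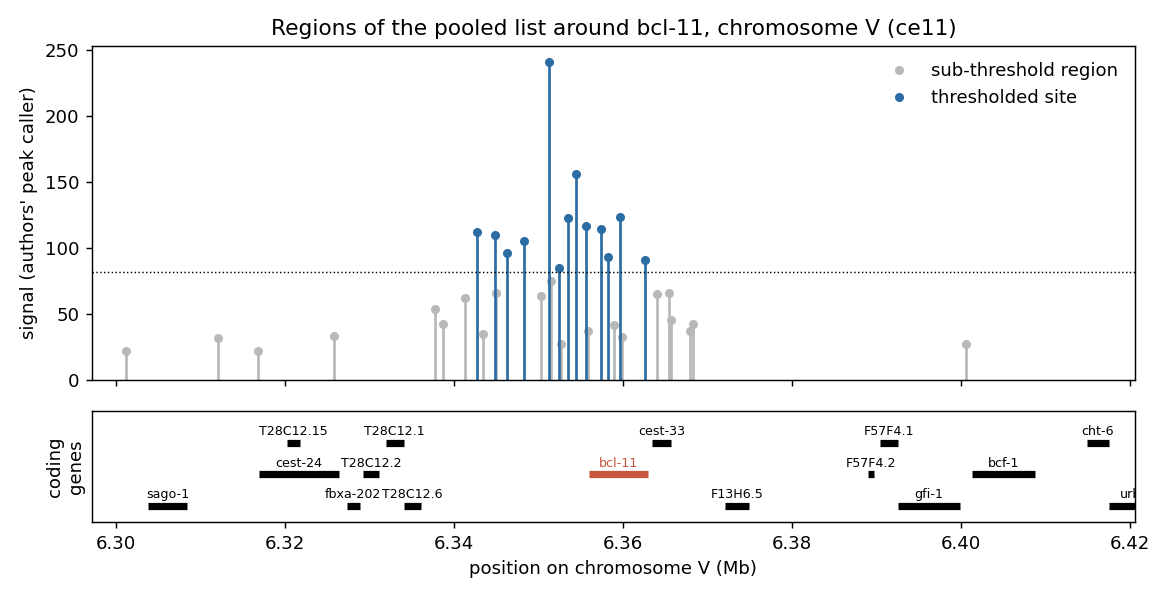
Summits of pooled regions within about 50 kb of bcl-11 on chromosome V of ce11 (x axis, Mb) with the authors' signal (y axis), sites in blue and sub-threshold regions in grey, above the protein-coding genes. The 13 sites lie in 1 block of 29 regions from 6337689 to 6368279.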

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

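Tests without sites near tRNA, snRNA and snoRNA genes, on the nuclear genome, with protein-coding starts and without the regions around bcl-11, and each replicate alone for bcl-11 and for single sites, were chosen only after the results were seen. The promoter share kept its direction and its call under all 9 alternatives run, with odds ratios from 1.95 to 4.55. The autosome centre share did so too, from 1.31 to 1.84, and replicate overlap ranged from 63% to 74.6%. Against the background TGACCA passed under none, and its odds ratio ranged from 0.765 to 1.28. The X share of 21.5% turned to the other side against the strongest sub-threshold regions (odds ratio 0.973), which were themselves richer in X. It lost its call with promoter sites alone (20.9%) and without sites near small RNA genes (19%). The number of lists past the threshold was 7 with the 532 strongest sites and 4 with genes that have a permissively called region, where fewer sites or genes entered the test. It was 13 with each replicate alone, 10 and 18 with shorter and longer promoter windows, and 18 with nearest starts. Of the 13 lists 3 passed under every alternative: tRNA, snRNA with snoRNA, and ribosomal protein genes. Matched for GC content and promoter window, 414 words passed, with a background of 2122 regions. Leaving out a replicate gave 8 to 12 sites near bcl-11, and the cause was not tested. With nearest starts the hypodermis list moved to 3.86 and the long intergenic RNA list to 2.34, and the cause was not tested. Among results for single chromosomes, lists, words and sites 557 kept their side of the threshold, 33 lost it and 16 gained it. Direction turned for the 2 lists just named, which passed after the turn, and among the 557 another 44 odds ratios crossed 1 without passing on either side. Of 83 named sites 71 lay among the 1065 highest of both replicates. No paired analysis was possible because the series has only 1 group. Depth per library is unknown, so whether sub-threshold regions fell short for lack of reads cannot be said.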

Other observations

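The tests of gene families grouped by name prefix were chosen only after the results were seen, and so were the windows around bcl-11, at 20 kb and longer, while the bounds of all the tests of explanations were written before their values were seen. Among gene families grouped by name, those of the nuclear pore, of translation initiation and of the Mediator complex had the lowest p. Of 26 npp genes, for nucleoporins, 6 were bound, led by npp-6 and npp-8 (odds ratio 7.36, 2.95 to 18.4, exact p = 0.000431, adjusted p = 0.0505). Of 25 eif genes, for translation initiation factors, 5 were bound, led by eif-3.E and eif-3.I (6.12, exact p = 0.00259, adjusted p = 0.152). Of 20 mdt genes, for Mediator subunits, 4 were bound, led by mdt-8 and mdt-6 (6.12, exact p = 0.00702, adjusted p = 0.232). None of the 117 families passed the adjusted threshold. Families already tested in the fixed lists, such as those of ribosomal proteins, collagens and C-type lectins, were not among them.

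Sites gathered at nuclear tRNA genes, and reads shared between identical gene copies are a technical explanation. Were they the whole cause, tRNA genes whose sequence occurs once in the genome would rarely have a site. Of these, 15 of 140 had one (10.7%, 6.60 to 16.9), against 98 of 472 with identical copies (20.8%, exact p = 0.00629), a ratio of 0.516 (0.310 to 0.859), and single-copy genes alone gave an odds ratio of 8.32 (4.53 to 15.3), which argues against shared reads as the whole cause, though near-identical copies were not counted and the higher share in repeated genes may still come from them. GC content is another. Over 10 strata of GC count the odds ratio was 8.04 (6.23 to 10.4), against 11.1 without strata. This argues against base composition as the whole cause, though not as a part of it. Signal at highly transcribed open chromatin in any immunoprecipitation stays open, since control libraries were not analysed here, and no biological explanation was tested because the design has 1 group.

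The dense sites at bcl-11 may come from extra copies of the locus in the transgene. The 20 kb centred on the gene held 20 pooled regions, against a genome median of 4 per 20 kb, a ratio of 5, above the bound of 3 per 20 kb set for transgene copies. Of 5010 fixed windows 2 held as many, and 1 of these was the window with the centre of bcl-11. Of the fixed 20 kb windows that the gene touches, the one with its centre held 21 regions and the other 6. Over the gene with 20 or 25 kb on each side, lengths for which no bound was set, the same 29 regions gave ratios of 2.90 and 2.42. Among windows of those lengths, with the locus itself not left out, 3 of 2132 and 21 of 1758 held as many. The windows were chosen after the dense sites were seen, so passing the bound at 20 kb adds little. Counts of regions are not copy numbers and cannot tell extra copies from binding of the protein at its own gene. The extent of the transgene was not used here. The 20 kb centred on unc-119 held 8 regions, and 757 of the 5010 windows held as many or more, which lies between the bounds of 1.5 and 3 times the median and leaves extra copies open there too, and no biological explanation was tested.

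The promoter excess of the sites may in part follow from ranking regions by signal where open promoters give more reads. Among sub-threshold regions alone the promoter share was 47.2% in the lowest decile of signal and 65.5% in the highest, a ratio of 1.39 (1.31 to 1.47). This lay between the bound of 1.5 set for such a ranking and the bound of 1.1 set against it, so the explanation cannot be told apart from binding at promoters. No biological explanation was tested.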
